A study of Escherichia coli with 5 samples.

How the data were processed

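Total RNA was taken from 6 Escherichia coli strains grown in LB broth at 37 °C to an optical density of 0.5 at the wavelength the labels name, after overnight cultures were diluted 100-fold, per the labels. All strains were derivatives of MC4100, a laboratory K-12 strain that lacks the argF to lac region, and all carried a sulA allele. They were the parent strain (WT here), strains with an insertion in ndk or in dcd, a recA730 strain, and recA730 strains with the ndk or the dcd insertion. RNA was isolated with a commercial bacterial RNA kit and labelled with Cy3 or Cy5, per the labels. The strains were compared in pairs on 2-colour arrays, which gives 5 comparisons on 26 arrays. The arrays come from 13 biological replicates, 3 each for recA730 against WT, ndk against WT and recA730 ndk against recA730, and 2 each for dcd against WT and recA730 dcd against recA730, with each replicate hybridised on 2 arrays with the dyes swapped. The dye of each strain and the number of the biological replicate were taken from the array names the authors deposited. Replicate and dye are not given elsewhere in the sources used here.

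The authors deposited 1 scanner table per array, whose signal columns hold spot intensity on a linear scale with a local background for each dye, per the file headers. Another deposited column gives the percent of saturated pixels of each spot. The authors also deposited a table of processed log2 ratios with 1 value per probe and comparison. Its scale, centring and direction are not stated, and were found by setting it against the scanner ratios. Each column follows the log2 ratio of mutant over parent, with a slope between 1.07 and 1.18 on the values computed here and a correlation across genes between 0.93 and 0.98. Its column medians are 0.003 for recA730 against WT, 0.01 for ndk against WT, 0.03 for dcd against WT, 0.03 for recA730 ndk against recA730 and 0.04 for recA730 dcd against recA730, so the columns are centred near 0. Which correction and centring made these values is not given in the sources used here. The scanner tables carry no slide, scan date or software version.

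Each array holds 15744 spots, of which 3791 are negative and 459 positive controls. Of 10691 gene probes, 4234 are named by a K-12 locus and 6457 by a locus of another E. coli strain. The 31 K-12 probes shared by more than 1 locus were left out, as were probes for other strains, which leaves 4203 probes for 4179 loci. Loci were given their current symbols from a gene table of assembly ASM584v2, which matched 4027 of them, and the other 152 keep the name in the deposited tables. The build behind the array design is not given in the sources used here, so no coordinates are printed and the table was used for names and for which genes neighbour each other.

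Background was corrected with limma's normexp method with an offset of 50 on the mean signal and the median local background. Ratios were normalized within each array by loess with the control spots at weight 0, and no step was applied between arrays. A spot counted as well above background where its background-subtracted signal passed the median of the array's negative controls by 2.6 scaled median absolute deviations. The scaling makes this deviation equal an SD for normally distributed values. Probes were kept where either channel was well above background on at least 50% of the arrays of 1 comparison or more. That leaves 4124 genes and removes 55. The probes of a gene were averaged, and 22 genes have more than 1 probe. All ratios are mutant over parent, and the 2 dye-swapped arrays of a replicate were averaged, so that each biological replicate counts once. Where a gene was not well above background on any array in 1 strain, only a bound would be given, and no gene named here needed one.

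The 13 replicate values were fitted with limma (version 3.58.1, in R 4.3.3), with 1 coefficient per comparison, 8 residual degrees of freedom and empirical Bayes moderation, and p-values were adjusted by Benjamini and Hochberg over the genes tested. Standard errors (SE) are those of this fit. A gene counts as changed at an adjusted p under 0.05. Whether an insertion acted differently in the recA730 and the WT background was tested as a contrast of 2 coefficients. Genes named in the text were taken from recA, lexA, ndk, dcd, the neighbours of the disrupted genes and 4 other damage-response genes in every comparison. To these were added the 10 largest rises and falls past the threshold with the same sign in every replicate, and up to 4 members with the largest change of each gene list that was called or had at least 3 changed members. For the 2 background contrasts they are the 5 largest changes of either sign past the threshold. The comparisons, this rule, 26 gene lists and the alternatives of processing were fixed before the data were examined. Lists were tested with camera with a preset correlation of 0.01 and adjusted over the 26 lists, and tested again with an estimated correlation and with fry, which asks whether a list's genes move on balance in 1 direction.

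The number of arrays limits the precision. The median K-12 signal per array lay between 698 and 5075.5 in the red channel and between 870.5 and 5029 in the green, against median local backgrounds of 48 to 155. Between 94.7% and 98.5% of K-12 spots were well above background, and 27 or fewer were saturated per array and channel. The dye-swapped arrays of a replicate correlated across genes at 0.55 to 0.91, except ndk against WT replicate 1 at 0.09 and recA730 ndk against recA730 replicate 1 at 0.21. The steps were tested on simulated arrays of 4124 genes, with changes of known size put into some. For recA730 against WT, 89.4% of the genes changed by 2 on the log2 scale and 62.7% of those changed by 1 were called. For recA730 dcd against recA730 these shares were 81.8% and 38.8%. Between 2.44% and 6.5% of calls per comparison were of unchanged genes. The simulated noise was drawn separately for each gene, with the same spread in all comparisons and little noise between dye swaps. In the fit of the real arrays the first component of the residuals held 56% of their variance. These shares therefore need not hold for the real arrays.

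Lists called by camera in a comparison were also refitted without each replicate, an alternative added after the data were seen. The alternatives fixed beforehand were other background corrections, median centring, scaling between arrays, no filter and a stricter one, a fit of all arrays with a dye term, each comparison alone, another variance moderation, the median over probes, the replicate number as a block, each replicate left out, and the deposited table of processed ratios. For the background contrasts, the replicate number as a block meant subtracting the comparisons by equal replicate number and fitting the differences alone. The scanner software had done no dye normalization, so the alternative from its signals was median centred here. The planned model with the slide as a block was not run because the tables name no slide.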

Results

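Messenger RNA levels were compared between E. coli strains on 26 two-dye arrays. The series asks how the SOS response, the set of DNA-damage genes held down by the LexA repressor, behaves when nucleotide pools change. Ndk makes nucleoside triphosphates from diphosphates, and Dcd deaminates dCTP to dUTP. The recA730 allele encodes a RecA protein that is active without DNA damage. There were 3 biological replicates for recA730 against WT, for ndk against WT and for recA730 ndk against recA730. There were 2 for dcd against WT and for recA730 dcd against recA730. Every replicate was hybridised on 2 arrays with the dyes swapped, and 4124 genes were tested. Between 94.7% and 98.5% of K-12 spots were well above background per array and channel, as were 48.7% to 62% of spots for other strains. The number of arrays limits the precision. The gene lists were tested 182 times over 5 comparisons and 2 contrasts. Camera called 63 of these tests, of which 1 held with an estimated correlation and 3 held with fry. Outside the LexA list 43 of the calls were in the 5 comparisons, and 31 of these ended when 1 replicate was left out.

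The comparison of recA730 with WT asks which genes are expressed more when RecA is constitutively active. In recA730, recA (b2699) rose by a log2 ratio of 3.78 ± 0.39 (SE, n = 3), a 13.7-fold rise. The recombination gene recN (b2616) rose by 3.75 ± 0.31, yebG (b1848) by 3.66 ± 0.33, sbmC (b2009) by 2.19 ± 0.24 and dinI (b1061), whose product modulates RecA, by 3.60 ± 0.31. The genes of the mutagenic DNA polymerase V, umuD (b1183) and umuC (b1184), rose by 2.66 ± 0.24 and 1.97 ± 0.24. The division inhibitor gene sulA (b0958) rose by 1.62 ± 0.19, dinB (b0231), which encodes DNA polymerase IV, by 1.60 ± 0.16 and lexA (b4043) itself by 1.39 ± 0.24. Of 33 measured genes of the LexA list, 21 rose and 0 fell, and 29 rose when adjusted over the list alone. The 33 include insK, an insertion-sequence gene matched through its synonym dinS, which stood at −0.30 ± 0.19. The list's median was 1.38 (camera adjusted p = 2.30e-54), with an adjusted p = 0.0215 with an estimated correlation and 3.86e-04 by fry. The median per replicate was 1.37 ± 0.44 (SD, n = 3).

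In all, 33 genes rose in recA730 and 0 fell by limma's adjusted test, with 268 genes at an unadjusted p under 0.05 where chance gives 206.2. Of the 33, 12 were outside the LexA list. They included yebF (b1847) at 3.43 ± 0.33, bssS (b1060) at 2.10 ± 0.25 and the purine salvage gene gpt (b0238) at 1.94 ± 0.27. The periplasmic acid chaperone genes hdeA (b3510) and hdeB (b3509) rose by 1.78 ± 0.27 and 1.66 ± 0.24, and hdeD (b3511) rose by 1.12 ± 0.20. The others, chosen after their values were seen except for yjbJ at 1.38, were bamE at 1.73, the nucleoid protein gene hns at 1.70, yeeA at 1.36, tmaR at 1.11 and yfjF at 0.94. The count was 16 with median centring, 17 without replicate 1 and 20 without replicate 3. Scaling between arrays gave 36, and a fit of all arrays gave 49, of which 47 rose and 2 fell.

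Other lists shifted in recA730 by camera, and each call was lost with an estimated correlation. Acid resistance genes had a median of 0.34, with 3 of 12 called and 4 adjusted over the list alone (adjusted p = 1.82e-05, and adjusted p = 0.402 with an estimated correlation). Genes of the RpoS general stress response had a median of 0.32, with 1 of 32 called (adjusted p = 1.82e-05, and adjusted p = 0.402 with an estimated correlation). Iron uptake genes had a median of −0.52, with 0 of 43 called (adjusted p = 9.88e-09, and adjusted p = 0.566 with an estimated correlation). The siderophore receptor gene cirA (b2155) stood at −0.87 ± 0.39 and the enterobactin synthesis gene entE (b0594) at −0.86 ± 0.58. Cryptic prophage genes had a median of −0.37 (adjusted p = 5.32e-06, and adjusted p = 0.831 with an estimated correlation). Ribosomal protein genes had a median of −0.19 (adjusted p = 0.00224, and adjusted p = 0.888 with an estimated correlation). Medians were 0.27 for flagella and chemotaxis (adjusted p = 0.0175, and adjusted p = 0.888 with an estimated correlation) and 0.21 for histidine and tryptophan synthesis (adjusted p = 0.0178, and adjusted p = 0.402 with an estimated correlation). The acid resistance, RpoS and iron uptake calls held without each replicate. Others ended, for flagella without replicate 2 (median 0.02), for ribosomal proteins without replicate 1 (−0.03), for cryptic prophage genes without replicate 3 (−0.10), and for histidine and tryptophan synthesis without replicate 1 (0.13) or 3 (0.19).

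**Figure D1:**
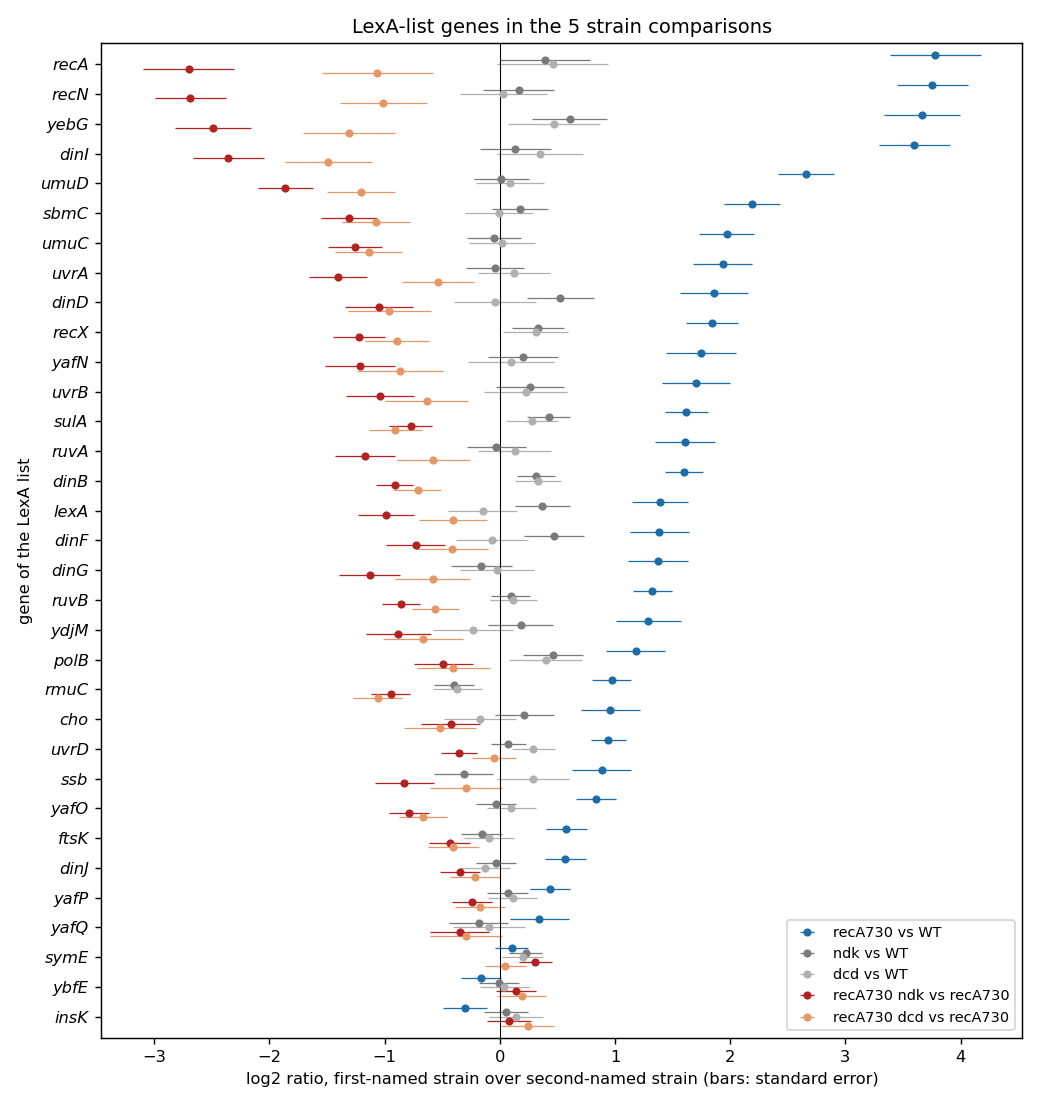
Log2 ratio of mutant over parent (horizontal, points, with SE as bars) for the 33 measured genes of the LexA list in each of the 5 comparisons. The list's median was 1.38 in recA730 against WT, −0.91 in recA730 ndk against recA730 and −0.58 in recA730 dcd against recA730.

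The comparison of ndk with WT asks what loss of Ndk changes while RecA is regulated normally. The disrupted gene ndk (b2518) fell by 5.08 ± 0.30 on the log2 scale (SE, n = 3), a 33.9-fold fall, and was the 1 gene called. At an unadjusted p under 0.05 there were 262 genes. A fit of all arrays called 4. Among damage-response genes, recA stood at 0.39 ± 0.39, sulA at 0.42 ± 0.19, lexA at 0.37 ± 0.24 and umuD at 0.01 ± 0.24. The neighbours rlmN and pbpC stood at −0.48 ± 0.16 and −0.11 ± 0.21. None of these passed the test, which does not show that they were unchanged. The LexA list had a median of 0.13 with 0 of 33 called, also adjusted over the list alone (camera adjusted p = 0.0608, and adjusted p = 0.794 with an estimated correlation). Its median per replicate was 0.12 ± 0.11 (SD, n = 3). Camera's adjusted p passed the threshold under 5 alternatives, with medians of 0.09 to 0.18, and without replicate 3, with 0.07.

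Iron uptake genes were lower in ndk, with 0 of 43 above WT and a median of −0.98. None was called over all genes and 22 were called adjusted over the list alone (camera adjusted p = 7.61e-23, and adjusted p = 0.293 with an estimated correlation). Enterobactin genes entA (b0596) and entE stood at −1.61 ± 0.54 and −1.50 ± 0.58. Ribonucleotide reduction genes had a median of 0.41, with nrdI (b2674) at 0.99 ± 0.25 and nrdA (b2234) at 0.84 ± 0.28. Adjusted over the list alone, 3 were higher and 1 lower (adjusted p = 0.00576, and adjusted p = 0.293 with an estimated correlation). De novo purine synthesis genes had a median of −0.45 (adjusted p = 7.89e-04, and adjusted p = 0.621 with an estimated correlation). Acid resistance genes had a median of 0.50 (adjusted p = 7.65e-05, and adjusted p = 0.388 with an estimated correlation). RpoS genes had a median of 0.35 (adjusted p = 2.01e-07, and adjusted p = 0.293 with an estimated correlation). Replicate 3 carried much of the size. Without it the medians were −0.64 for iron uptake, 0.15 for acid resistance and 0.23 for RpoS genes, all still called, and −0.19 for de novo purine synthesis, no longer called. The purine median was −0.69 without replicate 1. The ribonucleotide reduction call ended without replicate 1 (median 0.29) or 2 (0.42).

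Further lists were called in ndk by camera, and each call was lost with an estimated correlation. Colanic acid and curli genes had a median of 0.51 (adjusted p = 9.80e-06, and adjusted p = 0.621 with an estimated correlation), but replicate 3 alone carried it. Its replicate medians were 0.02, −0.11 and 1.66, the median without replicate 2 was 0.86 and without replicate 3 it was −0.02, with no call. Flagella and chemotaxis genes had 0.33 (adjusted p = 5.90e-04, and adjusted p = 0.621 with an estimated correlation), with 0.51 without replicate 2 and 0.11 without replicate 3. TCA cycle genes had 0.29 (adjusted p = 0.027, and adjusted p = 0.621 with an estimated correlation), although aceE and aceF, of pyruvate dehydrogenase, stood at −1.39 ± 0.64 and −1.37 ± 0.60. Anaerobic respiration and fermentation genes had 0.14 (adjusted p = 0.00576, and adjusted p = 0.621 with an estimated correlation). DNA replication genes had −0.19 (adjusted p = 0.0125, and adjusted p = 0.61 with an estimated correlation). The TCA cycle call ended without replicate 2 (0.14), with 0.59 without replicate 1 and 0.11 without replicate 3. The anaerobic call ended without replicate 1 (0.05), and the DNA replication call without replicate 1 (−0.18) or 3 (−0.09). The dye-swapped arrays of replicate 1 correlated at 0.09 across genes, which are not independent replicates. The biological replicates of ndk against WT correlated at −0.20 to 0.10 over all genes, and those of recA730 ndk against recA730 at −0.55 to 0.70. They correlated at 0.29 to 0.56 in recA730 against WT, 0.26 in dcd against WT and 0.31 in recA730 dcd against recA730. Replicate 3 of ndk against WT correlated at 0.81 and 0.66 with replicates 2 and 3 of recA730 ndk against recA730, more than with its own.

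The comparison of dcd with WT asks what loss of dCTP deaminase changes while RecA is regulated normally. The disrupted gene dcd (b2065) fell by 2.21 ± 0.31 on the log2 scale (SE, n = 2). Where its probe lies relative to the insertion is not given. Also called were the galactose regulator gene galS (b2151), which fell by 1.98 ± 0.30, yddB (b1495), which fell by 1.31 ± 0.20, mtfA (b1976), which fell by 1.17 ± 0.14, and the carbon-flow regulator gene cra (b0080), which fell by 1.12 ± 0.16. No gene rose, and 219 genes had an unadjusted p under 0.05. The neighbours asmA (b2064) and udk stood at −0.72 ± 0.24 and 0.07 ± 0.38, and ndk at −0.84 ± 0.37. None of these passed the test. These 5 calls became 0 without either replicate, and 0 under 5 alternatives of the processing. A fit of all arrays gave 18.

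The LexA list had a median of 0.10 in dcd, with 0 called, also adjusted over the list alone (camera adjusted p = 0.0232, and adjusted p = 0.839 with an estimated correlation). Its median per replicate was 0.12 ± 0.01 (SD, n = 2), recA was at 0.46 ± 0.48 and lexA at −0.15 ± 0.30. Camera's call ended with median centring, with a median of 0.06, and without replicate 1, with 0.11 and an adjusted p of 0.296. Iron uptake genes had a median of −0.76, with 42 of 43 lower and 9 called adjusted over the list alone (adjusted p = 1.04e-24, and adjusted p = 0.434 with an estimated correlation). Among them cirA stood at −2.13 ± 0.48 and the siderophore receptor gene fiu (b0805) at −1.85 ± 0.43. De novo pyrimidine synthesis genes had a median of 0.33, with pyrI and pyrB at 0.65 ± 0.31 and 0.64 ± 0.38 (adjusted p = 0.00124, and adjusted p = 0.434 with an estimated correlation). The iron uptake call held with either replicate alone. The pyrimidine medians of the replicates were 0.10 and 0.53, and the call ended without replicate 2. Ribonucleotide reduction genes were not called by camera in dcd, with a median of 0.01 and a mean of −0.06 (adjusted p = 0.856). Adjusted over that list alone 2 were higher, nrdA at 1.48 ± 0.34 and nrdB (b2235) at 1.11 ± 0.32, and nrdI was lower at −1.08 ± 0.31. These 3 genes were chosen here after their values were seen, and none passed the test over all genes.

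Further camera calls in dcd were lost with an estimated correlation. Medians were 0.22 for de novo purine synthesis (adjusted p = 0.00201, and adjusted p = 0.662 with an estimated correlation) and 0.10 for dNTP and pyrimidine salvage (adjusted p = 0.0172, and adjusted p = 0.434 with an estimated correlation). They were 0.21 for RpoS genes (adjusted p = 0.00201, and adjusted p = 0.434 with an estimated correlation) and 0.27 for acid resistance, with 3 of 12 called adjusted over the list alone (adjusted p = 6.82e-04, and adjusted p = 0.434 with an estimated correlation). Heat shock genes had 0.25 (adjusted p = 3.92e-05, and adjusted p = 0.434 with an estimated correlation) and cryptic prophage genes −0.40 (adjusted p = 0.0062, and adjusted p = 0.87 with an estimated correlation). Genes of the region deleted in all the strains had 0.18 (adjusted p = 0.014, and adjusted p = 0.434 with an estimated correlation). No strain carries these genes, so this call cannot come from their own transcripts. A camera call with the preset correlation therefore need not show a change in expression. Each of the calls in this paragraph ended without 1 of the replicates. Replicates 1 and 2 differed in sign for de novo purine synthesis (−0.23 and 0.73), salvage (−0.10 and 0.25) and acid resistance (−0.12 and 0.81). They had 0.48 and 0.01 for heat shock, 0.08 and 0.18 for RpoS genes, −0.29 and −0.39 for cryptic prophage genes and 0.13 and 0.20 for the deleted region.

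The comparison of recA730 ndk with recA730 asks what loss of Ndk does where RecA is constitutively active. Damage-response genes were lower in the double mutant. The gene recA fell by 2.70 ± 0.39 on the log2 scale (SE, n = 3), recN fell by 2.69 ± 0.31, yebG fell by 2.49 ± 0.33, dinI fell by 2.36 ± 0.31, yebF fell by 2.19 ± 0.33 and umuD fell by 1.86 ± 0.24. The disrupted gene ndk fell by 4.72 ± 0.30, and its neighbours rlmN and pbpC stood at −0.25 ± 0.16 and −0.31 ± 0.21. Just short of the threshold were umuC at −1.26 ± 0.24 and dinB at −0.91 ± 0.16, each with an adjusted p of 0.0529, while sulA stood at −0.77 ± 0.19 and lexA at −0.99 ± 0.24. Of 33 LexA-list genes 5 fell over all genes, and 24 fell when adjusted over the list alone. The list's median was −0.91 (camera adjusted p = 1.56e-29, adjusted p = 0.138 with an estimated correlation, and 0.0083 by fry). The median per replicate was −0.92 ± 0.29 (SD, n = 3).

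In all 7 genes fell and 0 rose, with 524 at an unadjusted p under 0.05. The count depended on single replicates, being 318 without replicate 1 (214 up, 104 down, with 21 of the LexA list down), 2 without replicate 2 and 3 without replicate 3. It was 1 with the scanner software's signals, 1 with scaling between arrays and 0 with the comparison fitted alone, against 13 without background subtraction, 13 with another variance moderation and 38 in a fit of all arrays. The dye-swapped arrays of replicate 1 correlated at 0.21 across genes. Replicate 1 ran opposite to the others over all genes, correlating at −0.55 with replicate 2 and −0.14 with replicate 3, while replicates 2 and 3 correlated at 0.70. The first component of the residuals held 56% of their variance, and its largest loading, −0.63, was on this replicate. The LexA list's median was below 0 in all 3.

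Cryptic prophage genes, which are mostly silent remnants of phages, had a median of 0.75, with 37 of 40 higher and 0 called (adjusted p = 8.73e-10, and adjusted p = 0.708 with an estimated correlation). The Qin prophage genes rem (b1561) and ydfU (b1560) stood at 1.33 ± 0.61 and 1.28 ± 0.52. De novo purine synthesis genes had a median of −0.46 (adjusted p = 5.39e-05, and adjusted p = 0.708 with an estimated correlation), and guaA (b2507) stood at −1.07 ± 0.39. Their replicate medians were 0.34, −0.94 and −0.72. The median was −0.86 without replicate 1, and −0.16 without replicate 2, with no call. Iron uptake genes had −0.50 (adjusted p = 3.25e-08, and adjusted p = 0.708 with an estimated correlation). Colanic acid and curli genes had 0.52 (adjusted p = 0.00518, and adjusted p = 0.809 with an estimated correlation). Their replicate medians were −0.56, 1.46 and 0.78. The median was 1.24 without replicate 1, and the call ended without replicate 2 (0.03) or 3 (0.34). Heat shock genes had 0.25, with 3 called adjusted over the list alone (adjusted p = 0.00632, and adjusted p = 0.708 with an estimated correlation). Medians were 0.21 for anaerobic respiration and fermentation (adjusted p = 0.0374, and adjusted p = 0.708 with an estimated correlation) and −0.13 for arginine synthesis (adjusted p = 0.0493, and adjusted p = 0.708 with an estimated correlation). Cold shock genes, at a median of 0.17, were called by fry (adjusted p = 0.0272) and not by camera (adjusted p = 0.474). The iron uptake and prophage calls held without each replicate, with −0.97 for iron uptake without replicate 1, −0.15 without replicate 3, and 0.43 for prophage genes without replicate 3. Calls ended for heat shock without replicate 1 (0.23) or 3 (0.14), for anaerobic genes without replicate 1 (0.13) and for arginine synthesis without replicate 1 (−0.21) or 3 (−0.22).

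**Figure D2:**
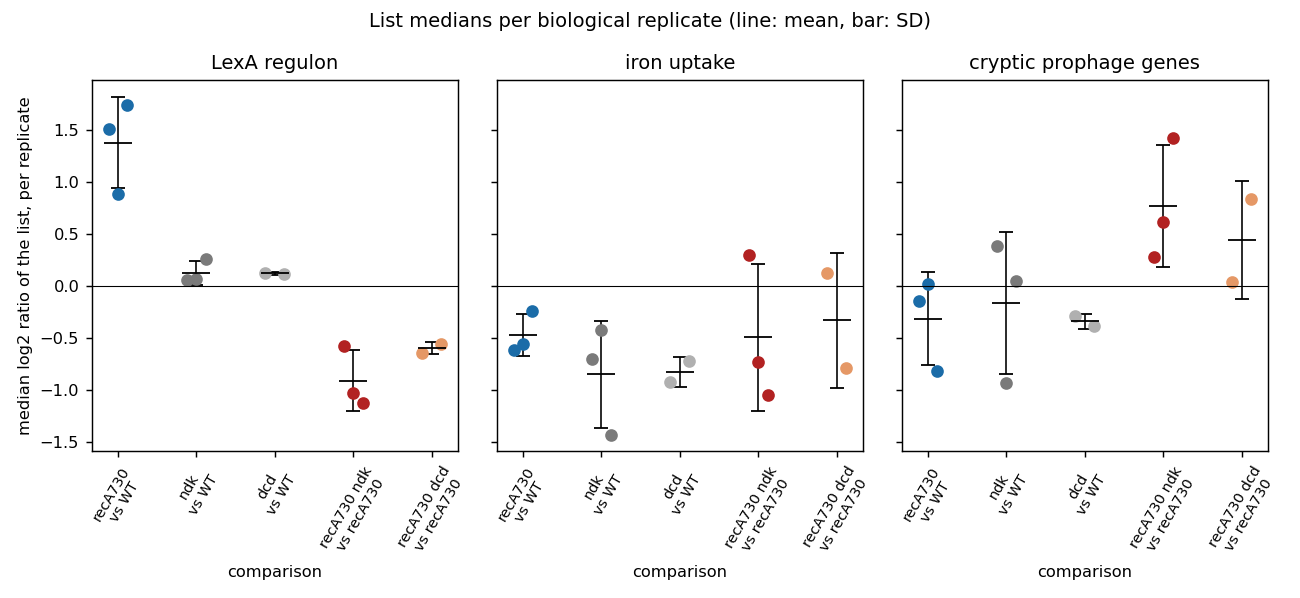
Median log2 ratio of mutant over parent (vertical) of the LexA, iron uptake and cryptic prophage lists in each biological replicate (points) of the 5 comparisons, with the mean as a line and the SD as a bar. For the LexA list the mean was 1.37 in recA730 against WT, −0.92 in recA730 ndk against recA730 and −0.60 in recA730 dcd against recA730.

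The iron uptake and cryptic prophage medians also varied between replicates. For iron uptake they ran from −1.05 to 0.29 in recA730 ndk against recA730 and from −0.80 to 0.12 in recA730 dcd against recA730, so the sign differed between replicates. In ndk against WT they ran from −1.43 to −0.43 and in dcd against WT from −0.93 to −0.73. For cryptic prophage genes they ran from 0.27 to 1.42 in recA730 ndk and from 0.03 to 0.84 in recA730 dcd against recA730. In recA730 against WT they ran from −0.83 to 0.02, in ndk against WT from −0.94 to 0.38, with opposite signs, and in dcd against WT from −0.39 to −0.29.

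The comparison of recA730 dcd with recA730 asks what loss of Dcd does where RecA is constitutively active. The disrupted gene dcd fell by 2.64 ± 0.31 on the log2 scale (SE, n = 2) and was the 1 gene called, with 285 at an unadjusted p under 0.05. LexA-list genes were lower in the double mutant, with a median of −0.58 and 30 of 33 lower. None was called over all genes, and 10 fell when adjusted over the list alone (camera adjusted p = 4.82e-13, and adjusted p = 0.354 with an estimated correlation). Among these 10 were dinI at −1.49 ± 0.38, umuD at −1.21 ± 0.29, umuC at −1.14 ± 0.29 and sulA at −0.91 ± 0.23. The gene recA, at −1.06 ± 0.48, was not, with an adjusted p of 0.108 over the list. The median per replicate was −0.60 ± 0.06 (SD, n = 2). The call of dcd was lost without either replicate (dcd at −2.57 and −2.72). No gene was called without replicate 1, and without replicate 2 the 1 called gene was hyaB, named after its value was seen, which was higher at 1.96. The count was 0 with median centring, with scaling between arrays and with another variance moderation, and 4 to 9 under 3 others.

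The neighbours asmA and udk stood at −0.82 ± 0.24 and 0.01 ± 0.38, and ndk at −1.08 ± 0.37, and none passed the test. De novo pyrimidine synthesis genes had a median of 0.50, with pyrB (b4245) at 1.31 ± 0.38, pyrI (b4244) at 1.16 ± 0.31 and 2 called adjusted over the list alone (adjusted p = 6.32e-06, and adjusted p = 0.354 with an estimated correlation). Ribonucleotide reduction genes had a median of 0.11, with nrdA at 1.58 ± 0.34, nrdB at 1.29 ± 0.32 and 3 called adjusted over the list alone (adjusted p = 0.00337, and adjusted p = 0.354 with an estimated correlation). Both genes were also higher in dcd against WT, and their differences between the backgrounds, 0.10 ± 0.49 and 0.18 ± 0.45, did not pass the test. Salvage genes had 0.17 (adjusted p = 0.00182, and adjusted p = 0.354 with an estimated correlation) and de novo purine synthesis genes 0.29 (adjusted p = 0.00239, and adjusted p = 0.62 with an estimated correlation). Cryptic prophage genes had 0.43 (adjusted p = 6.32e-06, and adjusted p = 0.62 with an estimated correlation) and iron uptake genes −0.46 (adjusted p = 2.35e-05, and adjusted p = 0.62 with an estimated correlation). TCA cycle genes had −0.36, with gltA, for citrate synthase, at −1.46 ± 0.69 (adjusted p = 0.0101, and adjusted p = 0.62 with an estimated correlation).

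Medians were 0.20 for ribosomal proteins (adjusted p = 0.00593, and adjusted p = 0.793 with an estimated correlation) and −0.27 for arginine synthesis (adjusted p = 0.0312, and adjusted p = 0.354 with an estimated correlation). Genes of the deleted region had 0.09 (adjusted p = 0.0424, and adjusted p = 0.62 with an estimated correlation). All the strains lack these genes, so here too the call cannot come from their own transcripts. In this comparison the salvage and ribonucleotide reduction calls held with either replicate alone, the latter with medians of 0.24 and 0.18. The other calls outside the LexA list did not. Replicates 1 and 2 had 0.20 and 0.94 for de novo pyrimidine synthesis, −0.01 and 0.67 for de novo purine synthesis, 0.12 and −0.80 for iron uptake, −0.15 and −0.81 for the TCA cycle and 0.03 and 0.84 for cryptic prophage genes, and these calls ended without replicate 2. They had 0.44 and 0.02 for ribosomal proteins, whose call ended without replicate 1. Those of arginine synthesis (−0.29 and −0.19) and of the deleted region (0.07 and 0.15) ended without either. The other 6 lists were called by camera in none of the 5 comparisons. In recA730 against WT their medians were −0.04 for DNA repair outside the LexA list, −0.01 for envelope stress (mean 0.04), 0.07 for oxidative stress, 0.03 for branched-chain amino acid synthesis, 0.07 for methionine and cysteine synthesis and 0.12 for toxin-antitoxin pairs.

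Whether an insertion acted differently in recA730 and in WT was tested on the difference itself. For ndk the LexA list's difference had a median of −1.14, with 30 of 33 lower and 22 called adjusted over the list alone (camera adjusted p = 9.11e-40, adjusted p = 0.0579 with an estimated correlation, and 0.0363 by fry). For dcd the median was −0.69, with 31 of 33 lower and 0 called adjusted over the list alone (camera adjusted p = 2.14e-19, adjusted p = 0.295 with an estimated correlation, and 0.6 by fry). Over all genes limma called 0 for ndk, with 178 at an unadjusted p under 0.05, and 0 for dcd, with 83. Chance gives 206.2, so both lie below it. The fit shares its spread over all comparisons. The median SD between replicates ran from 0.18 in dcd against WT to 0.46 in recA730 ndk against recA730. A shared spread can be too wide for the former and too narrow for the latter. The ndk difference rests on the comparisons with the widest spread, at 0.39 and 0.46. Too narrow a spread would raise its count, so this does not account for the 178 genes. The ndk count was 12 in a fit of all arrays and 3 without recA730 ndk replicate 1. The dcd count was 252 with the replicate number as a block, which here fitted 2 paired differences alone.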

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

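No test in this part was chosen only after its result was seen.

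Differences between the recA730 and the WT background were called by camera for 6 lists under ndk and 10 under dcd. With an estimated correlation none was called, and with fry only the LexA list under ndk was. Apart from the LexA list they were not refitted without single replicates. The medians of the ndk difference were −1.14 for the LexA list, −0.20 for RpoS genes, −0.31 for acid resistance, 0.33 for heat shock, 0.38 for iron uptake and 0.95 for cryptic prophage genes. Those of the dcd difference were −0.69 for the LexA list, 0.18 for ribonucleotide reduction, −0.22 for RpoS genes, −0.24 for acid resistance, −0.35 for heat shock and 0.46 for iron uptake. They were −0.49 for the TCA cycle, −0.23 for arginine synthesis, −0.30 for histidine and tryptophan synthesis and 0.76 for cryptic prophage genes. In the ribonucleotide reduction list nrdA and nrdB were higher in both backgrounds, called only over the list alone. Its genes nrdD, nrdG, nrdE, nrdF, nrdH and nrdI, chosen after their values were seen, ran from −1.08 to −0.43 in dcd against WT. In recA730 dcd against recA730 these genes ran from −0.01 to 0.47.

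LexA-list genes were lower in both recA730 double mutants than in recA730. A dye bias would leave 1 orientation near 0, and the highest of the 4 orientation means was −0.48. A loess artefact would end with median centring, where the weaker median was −0.43. A general fall of bright genes would lower other genes of like signal, whose lower median was −0.0423. Loess had already brought genes of like signal near 0, so this value alone cannot show whether bright genes fell. The list's medians of −0.91 and −0.58 lay below it after the same correction. It stays open whether the comparisons shared recA730 extracts, which the labels do not state. Whether the comparisons with WT shared WT extracts was not examined. A shift in the WT cultures would move these comparisons together, and their iron uptake medians were −0.52, −0.98 and −0.76. Replicates of different comparisons correlated at −0.63 to 0.81 over all genes, so the comparisons need not be independent.

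Cryptic prophage genes had a median of 0.75 in recA730 ndk against recA730. Leftover genomic DNA would raise genes of like signal as well, whose median was 0.10 with an SD of 0.07 over draws. Normalization of dim spots would raise probes for other strains of like signal, whose median was 0.0089 with an SD of 0.05. Both values lie far below the list's median. Loess had already brought spots of like signal near 0, so neither value can show whether such spots rose in general. They show only that the list lay above other spots of like signal after that correction. The call was lost with an estimated correlation, so a shared shift of these genes between cultures stays open, also one in the recA730 cultures. The list's median was −0.37 in recA730 against WT and 0.43 in recA730 dcd against recA730.

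Probes for other E. coli strains also gave signal in these K-12 samples. A median of 55.1% of their spots were above background per array and channel (48.7% to 62%), against 4.02% of negative controls (1.27% to 13.5%). Among them 1 probe was called in recA730 against WT, a probe for recX at 1.78, and 1 in dcd against WT, a probe for galS at −1.57. The K-12 gene recX stood at 1.84 in recA730 against WT, and the K-12 gene galS also fell in dcd against WT. Probes named for another strain can therefore follow K-12 transcripts, and their signal need not be unspecific.

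Chance was examined with sign patterns of the replicates. For recA730 against WT 1 of 4 patterns gave as many genes (33 against at most 0), and the same held for ndk against WT (1 against 0) and recA730 ndk against recA730 (7 against 0). In ndk against WT the 1 gene was the disrupted ndk itself, which was far lower on every array. Turning the sign of 1 replicate had to remove it, so that count says nothing about chance. For the ndk difference the real count was 0, so that 10 of 10 splits of the 6 replicates had to reach it and their share says nothing. Apart from that, 1 other split gave 1186 genes, and so high a count points to a structure among the samples. The patterns are too few for a share under 0.05.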

How the results depend on the processing

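The LexA list's medians kept their direction and their side of camera's threshold in recA730 against WT (1.25 to 1.81), in recA730 ndk against recA730 (−1.09 to −0.78) and in both background differences (−1.47 to −0.92 and −0.84 to −0.49). These ranges cover 12 alternatives, of which the authors' table gives a direction but no test, and camera with its preset correlation. With an estimated correlation only recA730 against WT stays called (adjusted p = 0.0215), against 0.138 in recA730 ndk, 0.0579 for the ndk difference and 0.295 for the dcd difference. Of 3739 values of named genes under the alternatives, 3591 counted as the same. This meant the same direction and side, or no call in either fit whatever the direction. The 257 values from the authors' table were judged by a difference under the SD between replicates, which 233 met. Median centring moved the median of all genes by −0.11 in recA730 against WT and 0.15 in the dcd difference, where the LexA medians relative to all genes were 1.34 and −0.64. For the results below the cause was not tested, except that leaving out replicates reduces their number.

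Median centring gave 16 genes in recA730 against WT, 0 in dcd against WT and 0 in recA730 dcd against recA730. Its LexA medians were 0.11 in ndk against WT, now called, and 0.0570 in dcd against WT, no longer called. The scanner software's signals gave 0 genes in dcd against WT, 1 in recA730 ndk and 5 in recA730 dcd against recA730, and a called LexA median of 0.18 in ndk. Scaling between arrays gave 0, 1 and 0 genes in these comparisons and a called median of 0.0901. Trend and robust moderation gave 0, 13 and 0. The fit of all arrays gave 49 genes in recA730 (2 of them lower), 4 in ndk and 18 in dcd against WT, 38 in recA730 ndk and 9 in recA730 dcd against recA730, and 12 for the ndk difference. Each comparison alone gave 0 in dcd, 0 in recA730 ndk, 4 in recA730 dcd, and a called LexA median of 0.13 in ndk. Without background subtraction there were 13 genes in recA730 ndk and a called LexA median of 0.14 in ndk (adjusted p = 0.046, with 0.00605 to 0.0316 in the other alternatives that called it). The replicate number as a block gave 252 genes for the dcd difference, from 2 paired differences fitted alone. The authors' table gave LexA medians of 0.13 in dcd and −0.69 in recA730 dcd.

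With each replicate left out, counts ran from 17 to 26 in recA730 against WT, 0 to 0 in dcd against WT, 2 to 318 in recA730 ndk, 0 to 1 in recA730 dcd against recA730 (the 1 being another gene, and higher) and 0 to 3 for the ndk difference. LexA medians ran from 0.0657 to 0.27 in ndk and 0.11 to 0.12 in dcd. A comparison left with 1 replicate was assumed to vary like the others.

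The remaining alternatives were chosen after seeing the data. Of 43 camera calls outside the LexA list in the 5 comparisons, 12 held without each replicate, 31 ended without 1, and 6 medians changed sign. With each replicate left out these 6 ran from −0.0216 to 0.8556 for colanic acid and curli in ndk. In dcd they ran from −0.1038 to 0.2477 for salvage, −0.2328 to 0.7307 for de novo purine synthesis and −0.1157 to 0.8107 for acid resistance. In recA730 dcd against recA730 they ran from −0.0142 to 0.6670 for de novo purine synthesis and −0.7950 to 0.1250 for iron uptake. Without the 2 replicates whose dye swaps correlated under 0.3 there were 392 genes in recA730 ndk, 4 in recA730 dcd and 1 for the ndk difference. Without the 2 replicates that deviated most over all genes there were 1042, 4 and 466, and the LexA median in ndk was 0.0657. That choice removed replicates because of their own values, which inflates these counts, so they are no evidence. Equal replicate numbers of the ndk comparisons had deviations correlated at 0.55, −0.37 and 0.65 across genes. They were treated as pairs only in the alternative with the replicate number as a block. For dcd the correlation was 0.37, a single value, since with 2 replicates the deviations mirror each other. The planned model with slide as a block was not run, because no slide is given. Without insK the LexA medians ran from −1.17 for the ndk difference to 1.39 in recA730 against WT, and all 7 kept direction and side. Between 94.7% and 98.5% of K-12 spots were above background, but a spot above it need not show a transcript. Of 20 genes of the region the strains lack, 16 passed the filter. Of other-strain spots 55.1% were above background, but these can detect K-12 transcripts, so their share does not bear on this point.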

Other observations

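The sums of comparisons and the tests of hns and of neighbouring genes in this part were not planned, and both tests were chosen only after the results were seen.

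The double mutants were also set against WT by adding 2 comparisons. The LexA list then had a median of 0.53 in recA730 ndk and 0.83 in recA730 dcd (camera adjusted p = 3.61e-08 and 2.02e-23, and adjusted p = 0.461 and 0.255 with an estimated correlation). Between the double mutants, recA730 ndk minus recA730 dcd, it was −0.23 (camera adjusted p = 1.09e-06, and adjusted p = 0.387 with an estimated correlation).

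Genes outside the LexA list that rose in recA730 often lay beside its members. Within 2 positions of a listed gene, on the chromosome, 6 of 88 genes rose, against 6 of 3852 others (Fisher's exact test, two-sided, p = 8.68e-08). These were yebF, bssS, bamE, yjbJ, yeeA and yfjF, while tmaR and gpt lay 3 and 4 positions away, and hdeA, hdeB, hdeD and hns lay at least 55. Without insK, which entered the list through the synonym dinS, 6 of 86 near genes rose against 6 of 3855 others (Fisher's exact test, two-sided, p = 7.54e-08), and the hde genes lay at least 156 positions away. The rises may come from nearness on the chromosome to a LexA-list gene (such as transcripts running on past the list's genes). This is a hypothesis, since strand was not used and the limit of 2 positions was set after the genes were seen.

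Genes silenced by the nucleoid protein H-NS were set against the level of hns mRNA, because bgl, gsp and fim genes had been seen to move before the list was written. Over 13 replicates Pearson's r was −0.0167 (permutation p = 0.958) and Spearman's rho −0.0604 (permutation p = 0.85), with r = −0.0721 without the 2 farthest replicates. For the cryptic prophage list r was −0.54 (permutation p = 0.0537, adjusted over 4 relations 0.215). With deviations from the comparison means, the H-NS list had r = −0.3442 (permutation p = 0.246, adjusted 0.492, and −0.1914 without the 2 farthest) and rho = −0.4780 (permutation p = 0.103), and the prophage list had r = −0.0536 (permutation p = 0.861). None of the 4 relations passed the threshold, which does not show that none exists.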
